A study of Mus musculus with 8 samples.

How the data were processed

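Ileum RNA of LGR5-null mouse embryos was compared with ileum RNA of wild-type embryos on MEEBO arrays, glass arrays of 70-base mouse oligonucleotides. LGR5 is a receptor of the Wnt pathway that marks intestinal stem cells. Per the labels, total RNA was amplified to aminoallyl antisense RNA, coupled to Cy5 or Cy3 and hybridised null against wild type on the same array. The series holds 8 arrays, which are 4 pairs of a null and a wild-type embryo with 2 arrays each. On the first array of a pair the null sample carried Cy5 and on the second it carried Cy3. The design text states 3 parental couples for the 4 pairs, and which pairs share a couple is not given in the sources used here. The labels give embryonic day 18.5 for all arrays, and the design text gives day 18.5 to 19.

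The values deposited by the authors are 1 log ratio per probe and array. The base of the logarithm, the numerator and the normalization method are not given in the sources used here, and neither are spot intensities or backgrounds. The deposited values were taken as log2 ratios, so every fold below rests on that base. The array medians lay between -0.002 and 0.002, within the limit fixed in advance for using the values as deposited. The arrays of a pair, with their dyes swapped, correlated across probes at r = 0.312 to 0.783 (median 0.372), above 0, so the ratios were taken as already turned by the authors. Their direction was taken as null over wild type because the single Lgr5 probe lay below 0 on all 8 arrays. Lgr5 therefore set the sign of every ratio and does not check it independently. Arrays of different pairs correlated at a median of 0.117 with the same dye orientation and -0.024 with opposite orientations.

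The table holds 38467 probes, against 38784 stated in the labels, and 0 values were missing. The platform annotation gives 1 gene symbol for 22941 probes and none for 15526. No probe had several symbols. All 22941 were matched by gene identifier to the RefSeq gene table of mouse assembly GRCm38.p6, which gave 15123 symbols and changed none. Probes without a symbol are unnamed here, which does not mean that they lack a gene. The files name no genome build, so no coordinates are given. The tests used 36591 probes. The other 1876 belong to 4 identifier classes in which no probe has a gene in the platform annotation. That rule was set after the identifiers were seen and before any test.

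The 2 arrays of a pair were averaged, so that a dye effect cancels, and the pair was the replicate (n = 4). Means were tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, intercept only), 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. An exact sign-flip test of 4 pairs cannot go below p = 0.125. The number of arrays limits the precision, and pairs that share parents are not fully independent. Gene lists were fixed before the data were examined, 23 in all, each with at least 3 measured genes. They were tested on gene-level means of the probes with limma's camera at a preset correlation of 0.01 and adjusted over the 23 lists. With the sign of 1 or more pairs turned, the preset correlation still called 6 to 12 of the lists. Beside each call the adjusted p with an estimated correlation is given. The estimate was -0.001 for the Paneth, -0.008 for the cell cycle and 0.009 for the fibroblast list, below the preset value. For those lists a higher correlation between genes therefore does not account for the higher adjusted p of that setting. For the goblet list, by contrast, the estimate was 0.828. At a preset correlation camera takes its degrees of freedom from the number of genes. With an estimated correlation it uses the 3 residual ones of the 4 pairs. The adjusted p at the preset correlation therefore counts genes, not embryos, as the units. Differences between pairs were tested on the 8 arrays with 1 coefficient per pair and a dye term, by limma's moderated F-test.

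Named genes follow a rule also fixed in advance. It takes Lgr5, then in each direction up to 12 named probes past the threshold with the same sign in all 4 pairs. Where fewer than 6 qualified, it filled up to 6 with the largest mean ratios at unadjusted p under 0.01. From each list it takes up to 4 members past the threshold, over all genes or adjusted over the list alone, or otherwise the 2 members with the largest mean. From the test between pairs it takes the 6 named probes with the largest range. Any other gene named was chosen after its values were seen, which also holds for the list of posterior Hox genes and for genes that only illustrate the pair differences.

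The tests were checked on simulated data with the spread of the real probes. For the test of null against wild type, run on 36591 probes, 93 of 100 probes changed by 1 on the log2 scale were recovered and 100 of 100 changed by 2. It also called 12 of the 36391 unchanged probes. The changes were planted together on probes picked at random, with independent normal noise of the moderated spread. In the real data the Lgr5 probe, at -1.59 ± 0.47, had a limma adjusted p of 0.724. These recovery rates therefore do not show that real changes of such size would be called. For the lists, on 15123 genes, 20 of 20 lists shifted by 0.2 had an unadjusted p under 0.05, as had 6 of 200 unshifted ones. The simulated genes were independent, which real genes are not. For the test between pairs, 97 of 100 probes changed by 1 in a single pair were recovered and 99 of 100 changed by 2.

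Alternatives fixed in advance were centring each array on its median, scaling arrays to a common spread, either dye orientation alone, a random pair block with a dye term on the 8 arrays, leaving out each pair in turn, an adjusted p of 0.10, robust eBayes, weights per pair, gene-level values, an ordinary 1-sample test, an estimated list correlation, fry, and all probes of the listed genes. Chosen after seeing the data were leaving out probes whose 2 arrays of a pair differ by over 1, testing all probes of the file, and leaving out pairs 1 and 3 together. Under an alternative, a turned sign of a list or gene was counted as a reversal only if its value was past the threshold in either setting.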

Results

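The data are log2 ratios of ileum RNA from 4 pairs of mouse embryos of late gestation, each pair an LGR5-null against a wild-type embryo, with each pair hybridised on 2 arrays with the dyes exchanged. The study's title asks about altered cell lineage differentiation in the fetal gut without LGR5. Ratios are given as null over wild type, as mean ± SD over 4 pairs. The SD of all ratios on an array ran from 0.144 to 0.326, and the median SD of a probe between pairs was 0.0959.

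Lgr5, the targeted gene, was lower in the null sample of every pair. Its single probe gave log2 ratios of -1.61, -0.92, -1.92 and -1.93 in pairs 1 to 4, a mean of -1.59 ± 0.47 (SD, n = 4), or 0.331 of the wild-type level. The same probe settled the direction of all ratios, and whether it lies in the deleted part of the gene is not given in the sources used here. It did not pass the threshold over all probes (limma adjusted p = 0.724). With all 8 arrays and the pair as a random block, the adjusted p was 0.0118.

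No single probe passed the test of null against wild type. Of 36591 probes, 0 had an adjusted p under 0.05 in limma, and the lowest adjusted p was 0.480. At an unadjusted p under 0.05 there were 2003 probes, 852 higher and 1151 lower in null ileum, where the nominal rate gives about 1830. With the sign of 1 or more pairs turned, the number ran from 807 to 2191. The same sign in all 4 pairs was found for 5283 probes, 14.4% of those tested, where chance gives 12.5%. Gene-level values gave 0 of 15123 genes, and an ordinary 1-sample test 0 probes. The random-block fit gave 12 probes, 2 higher and 10 lower. The pair means of different pairs correlated weakly across probes, between -0.009 and 0.129.

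Among named probes with an unadjusted p under 0.01 and the same sign in all 4 pairs, 6 with the largest means in each direction are given. Lyz1, the lysozyme of Paneth cells, had a mean of 1.22 ± 0.59 (SD, n = 4) on 1 probe, or 2.32-fold, and 0.51 ± 0.44 on its other probe. St6galnac1, a sialyltransferase of mucin-type sugar chains, gave 0.91 ± 0.46, and Serpina10, a protease inhibitor, 0.63 ± 0.31. Ascl2, a transcription factor of intestinal stem cells, gave 0.58 ± 0.24 on 1 probe and 0.40 ± 0.16 on the other. Ccdc59 stood at 0.57 ± 0.28 on 1 probe and 0.33 ± 0.17 on the other. Lrp2bp stood at 0.53 ± 0.29, and its other probe gave 0.03 ± 0.08. Below 0, beside Lgr5, the same rule gave Mfap5, a microfibril protein, at -1.07 ± 0.32, or 0.476-fold, and Prss35, a protease-like protein, at -0.99 ± 0.49. In the same group, Mptx1, a mucosal pentraxin, gave -0.96 ± 0.50, Eln, the elastin gene, -0.81 ± 0.29, and Scyl2 -0.80 ± 0.42. None passed the threshold, with adjusted p from 0.724 to 0.784.

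**Figure D1:**
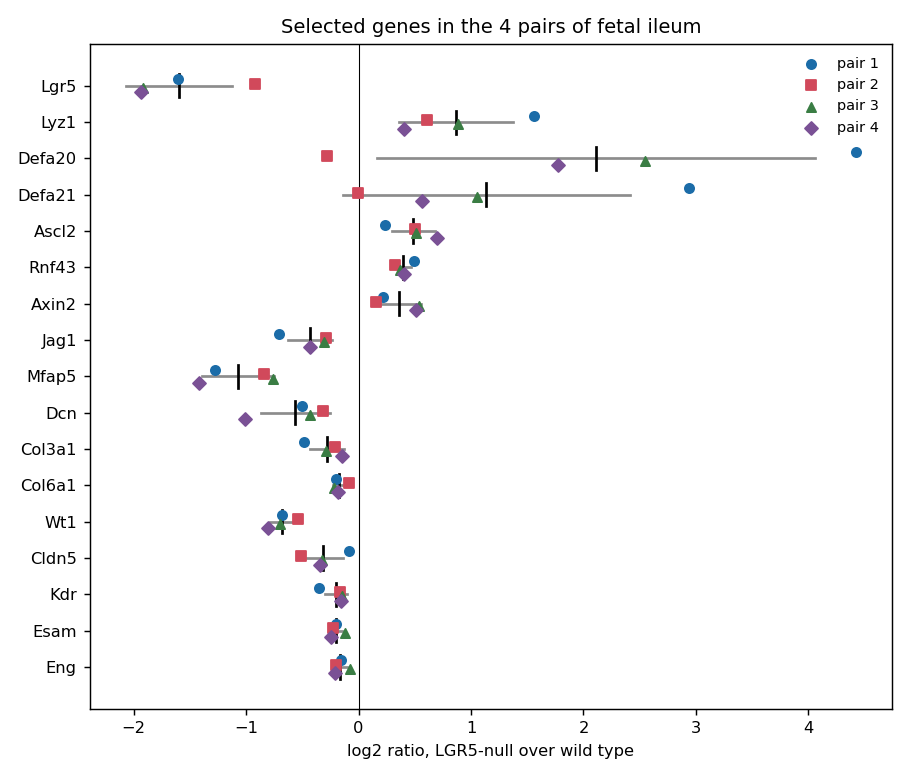
Log2 ratio of null over wild type for Lgr5 (probe) and for 16 genes of the fixed lists (mean of their probes), with 1 symbol per pair, the mean as a vertical tick and the SD as a grey bar (n = 4). Lgr5 lies below 0 in all 4 pairs, Rnf43 between 0.32 and 0.49, and Defa20 between -0.28 and 4.42.

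Paneth cell genes, the antimicrobial products of the crypt base, were shifted up in null ileum as a list (camera adjusted p = 0.000248). With an estimated correlation the adjusted p was 0.178. Of 14 measured members 12 had a mean above 0, 3 of them in all 4 pairs. Reg3g was above 0 in pair 1 alone, at 2.93, and Itln1 was below 0 in all 4 pairs, at -0.39 ± 0.33. Of the members, 0 passed the threshold over all genes or adjusted over the list alone, against 2 without pair 1. The list's median ratio was 0.26, 0.18, 0.47 and 0.11 in pairs 1 to 4, and its mean of 0.46 was 0.27 without pair 1. The largest means were those of the alpha-defensins Defa20, at 2.11 ± 1.95 (SD, n = 4), and Defa21, at 1.14 ± 1.28, and Defa20 ranged from -0.28 in pair 2 to 4.42 in pair 1. Lyz1 as a gene stood at 0.86 ± 0.51 and was above 0 in all 4 pairs. Alpha-defensins, and Lyz1 with Lyz2, are close relatives, and how far the 70-base probes separate them was not measured.

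Goblet cell genes, the mucus and secretory products of that lineage, were shifted down as a list (camera adjusted p = 2.67e-05), with an adjusted p = 0.586 with an estimated correlation. All 12 measured members had a mean below 0, and 0 passed the threshold over all genes or adjusted over the list alone. The shift was uneven, with pair medians of -1.05, -0.006, 0.06 and -0.30. Retnlb, a goblet cell cytokine-like protein, gave -0.81 ± 0.88 (SD, n = 4) and Klk1, a kallikrein, -0.74 ± 0.70. Pair 1, where the goblet genes were lowest, also had Hoxd10 at -3.81 and the Y-linked gene Eif2s3y at -4.56. The list of immediate early and stress genes had its highest pair median there, 0.55, and that of enteric neurons and glia its lowest, -0.45. Without pair 1 the mean of the list went from -0.40 to -0.15, with an adjusted p of 0.0189.

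The lists of the other epithelial lineages did not pass the threshold, which does not exclude a shift. Without pair 1 the enterocyte and lysosomal lists both had an adjusted p of 0.0542, with means of -0.02 and -0.05. Enteroendocrine genes had a camera adjusted p of 0.557, absorptive enterocyte genes 0.445, the endocytic and lysosomal genes of fetal ileal enterocytes 0.398 and tuft cell genes 0.924. None of their 24, 25, 14 and 9 measured members passed the threshold over all genes or adjusted over the list alone. The hormone genes Sst and Tac1 stood at -0.60 ± 0.58 and 0.21 ± 0.29 (SD, n = 4). Fabp1, which binds fatty acids in enterocytes, stood at 0.81 ± 1.19, with 2.52 in pair 3 and 0.70 in pair 4. Fabp1 is also a liver gene, and the liver list had medians of 1.95 and 0.32 in those pairs. Rbp2, which binds retinol, stood at 0.70 ± 0.47. The lysosomal lipase Lipa gave 0.17 ± 0.25 and the endocytic adaptor Dab2 0.15 ± 0.15. Plcb2 and Trpm5, of the taste-type signalling of tuft cells, gave 0.43 ± 0.79 and -0.33 ± 0.41. The tuft list had a median of -0.02 but a mean of 0.04, and its test pointed up.

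Among Wnt target genes, 3 were higher and 1 was lower in null ileum when adjusted over the list alone, and 0 of 22 over all genes. Ascl2 had a mean of 0.49 ± 0.19 (SD, n = 4; adjusted p over the list alone = 0.0175). Rnf43, a ubiquitin ligase that removes Wnt receptors, gave 0.40 ± 0.07 (0.00375), and Axin2, a feedback inhibitor of Wnt signalling, 0.36 ± 0.20 (0.0417). Jag1, a Notch ligand, gave -0.43 ± 0.19 (0.0222). Each of the 4 had the same sign in all 4 pairs. The list as a whole was not past the threshold (camera adjusted p = 0.0578). Stem cell genes without Lgr5, of which 2 of 17 passed adjusted over the list alone, Ascl2 and Rnf43, were likewise not past it (0.0563). Leaving out pair 1 gave adjusted p = 0.00759 for the Wnt targets and 0.0179 for the stem cell genes, which also passed without pair 2 (0.0416). The Wnt targets also passed with arrays scaled to a common spread (0.0413), and the stem cell genes with the random block (0.0338) and with all probes of the genes (0.0136), and both without pairs 1 and 3 (0.000934 and 0.0193). Over the 4 pairs both lists had an adjusted p = 0.586 with an estimated correlation. Leaving out pair 2, 3 or 4 left 1 passing member among the Wnt targets, and leaving out pair 3 left 1 among the stem cell genes.

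Notch pathway genes were not past the threshold (camera adjusted p = 0.0606), and 13 of 19 had a mean below 0. Dtx1, a Notch regulator, stood at -0.48 ± 0.37 (SD, n = 4), and Jag1 did not pass adjusted over this list alone (0.0576). The list was past the threshold without pair 3 (adjusted p = 0.0123) and on the arrays with the null sample in Cy5 alone (0.0338). Over the 4 pairs it had an adjusted p = 0.586 with an estimated correlation. Hedgehog and BMP genes had an adjusted p of 0.932, with Shh, the epithelial hedgehog ligand, at 0.30 ± 0.37 and Id3, a BMP target, at -0.21 ± 0.40. No member of either list passed over all genes or over the list alone, and 1 Notch gene did so over the list alone without pair 1.

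Cell cycle and DNA replication genes were shifted up by a small and even amount. The camera adjusted p was 5.51e-06, and with an estimated correlation the adjusted p was 0.146. Of 24 measured members 21 had a mean above 0, and the list's median ratio was 0.06, 0.07, 0.06 and 0.06 in pairs 1 to 4. None passed alone, over all genes or adjusted over the list alone. Mcm7, a subunit of the replicative helicase, gave 0.17 ± 0.11 (SD, n = 4) and Top2a, a topoisomerase, 0.16 ± 0.17.

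Fibroblast and matrix genes were shifted down in null ileum (camera adjusted p = 2.15e-06), with an adjusted p = 0.146 with an estimated correlation. Of 16 members 13 had a mean below 0, 9 of them in all 4 pairs, and the pair medians were -0.26, -0.16, -0.13 and -0.19. Adjusted over the list alone 4 members were lower, and over all genes 0. They were Mfap5 at -1.07 ± 0.32 (SD, n = 4), Dcn, a small matrix proteoglycan, at -0.56 ± 0.30, Col3a1, a fibrillar collagen, at -0.28 ± 0.15, and Col6a1, a microfibrillar collagen, at -0.17 ± 0.06. Without pair 1, 3 or 4 the number was 1, 1 or 2.

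Endothelial genes were also shifted down (camera adjusted p = 8.23e-06), with an adjusted p = 0.242 with an estimated correlation. All 10 members had a mean below 0, with pair medians of -0.10, -0.21, -0.14 and -0.10. Adjusted over the list alone 5 members were lower, and over all genes 0. The largest were Cldn5, a tight junction protein, at -0.32 ± 0.18 (SD, n = 4), Kdr, a VEGF receptor, at -0.20 ± 0.10, Esam, an adhesion molecule, at -0.20 ± 0.05 and Eng, a TGF-beta co-receptor, at -0.16 ± 0.06. The number was 0 without pair 2 or pair 4 and 2 without pair 3.

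Mesothelial genes did not pass the threshold as a list (adjusted p = 0.312). Wt1, a transcription factor of mesothelium and mesenchyme, was lower in every pair, at -0.68 ± 0.11 (SD, n = 4; adjusted p over the list alone = 0.000368, over all genes 0.656). It was the single passing member of 8, and without pair 2 there were 2. Smooth muscle genes were not past the threshold (adjusted p = 0.820, with an estimated correlation 0.959, but 0.000624 with a mean of 0.10 without pairs 1 and 3), with 0 of 11 members past the threshold either way, and 1 over the list alone without pair 4. Pln, a calcium pump regulator, stood at -0.21 ± 0.13 and Actg2, an actin of enteric muscle, at 0.12 ± 0.29. The list's median was 0.02 and its mean -0.01, with the test pointing down. Enteric neuron and glia genes were shifted down (camera adjusted p = 0.00555), with an adjusted p = 0.586 with an estimated correlation and an adjusted p of 0.755 without pair 1. None of 15 passed over all genes or over the list alone, with the glial gene S100b at -0.30 ± 0.20 and the neuropeptide gene Vip at -0.29 ± 0.28.

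Markers of blood, neighbouring organs and handling were uneven between the pairs. Pancreas genes were shifted up (camera adjusted p = 0.00122), with an adjusted p = 0.586 with an estimated correlation and 0.346 without pair 3, where their median was 1.40. Liver genes were shifted up (0.00501), with an adjusted p = 0.655 with an estimated correlation and 0.669 without pair 3, where their median was 1.95. Erythroid genes were shifted up (0.0173), with an adjusted p = 0.660 with an estimated correlation and 0.679 without pair 3, where their median was 1.31. Leukocyte genes were shifted up (0.00222), with an adjusted p = 0.586 with an estimated correlation and 0.299 without pair 1. Immediate early and stress genes were shifted up (0.00132), with an adjusted p = 0.586 with an estimated correlation, and a median of 0.55 in pair 1. Without pair 1 their mean went from 0.21 to 0.065 and the adjusted p was 0.0344, and on the arrays with the null sample in Cy5 alone it was 0.121. None of the 11, 14, 12, 14 and 15 members of these lists passed over all genes or over the list alone.

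For each gene named from these 5 lists the SD between pairs exceeded the mean. Pnliprp1 and Ctrb1, of the exocrine pancreas, gave 1.24 ± 1.60 and 0.97 ± 1.32 (SD, n = 4), and the fibrinogen genes Fga and Fgg 0.73 ± 0.92 and 0.68 ± 1.21. The erythroid factor Klf1 gave 0.53 ± 0.72 and the globin gene Hbb-b2 0.46 ± 0.92. Aif1 and Laptm5, of leukocytes, gave 0.20 ± 0.26 and 0.15 ± 0.20, and the early response genes Fos and Atf3 0.65 ± 0.98 and 0.48 ± 0.82. Sex-linked genes did not pass the threshold as a list (adjusted p = 0.164), and 0 of 5 members passed. Genes near Lgr5 on its chromosome did not pass as a list (0.558), and 0 of 28 passed over all genes or over the list alone, with Kcnmb4 at -0.40 ± 0.51.

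**Figure D2:**
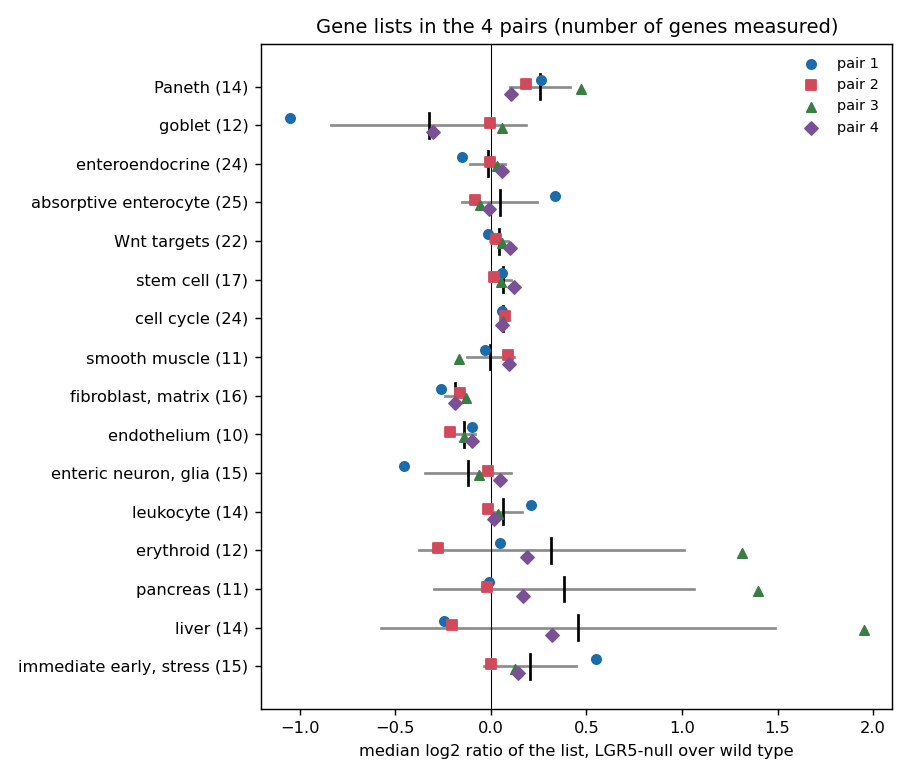
Median log2 ratio of null over wild type of the measured genes in 16 of the 23 lists, with 1 symbol per pair, the mean of the pair medians as a vertical tick and their SD as a grey bar (n = 4). The fibroblast and endothelial medians lie below 0 in all 4 pairs, while the liver median lies at 1.95 in pair 3 and at -0.25 in pair 1.

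The pairs differed from each other by more than the error between arrays of a pair at 8384 probes (limma moderated F-test, adjusted p under the threshold), 22.9% of those tested. That error is technical, so ordinary variation between embryos is enough to pass this test, and it says nothing on genotype. Without pair 1 the number was 1564, without pair 2 it was 5293, and without the dye term 5019. The largest range was that of Eif2s3y, a Y-linked gene, at -4.56 in pair 1, 0.01 in pair 2, 0.90 in pair 3 and -0.04 in pair 4 (adjusted p = 2.35e-05). Kdm5d, also Y-linked, was at -2.42 in pair 1. Defa20 ranged from -0.28 to 4.42 (4.82e-05) and Defa31, another alpha-defensin, from -1.38 to 2.50 (2.56e-05). In pairs 1 and 4 Defa31 stood at -0.41 and -1.38, where Defa20 stood at 4.42 and 1.77. Reg3b, an antimicrobial lectin of the gut, was at 2.40 in pair 1 and -1.59 in pair 3 (1.01e-05). Zg16, a goblet cell lectin, was at -2.86 in pair 1 and 1.00 in pair 3 (2.58e-05).

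Hoxd10, a posterior Hox gene, stood at -3.81 in pair 1 and between -0.17 and 0.10 in the others (adjusted p = 2.56e-05). Of 15 measured posterior Hox genes, a set chosen after the value of Hoxd10 was seen, 6 lay below -0.5 in pair 1, against 0, 1 and 0 in pairs 2 to 4. They included Hoxa11 at -2.61 and Hoxd9 at -1.93. Hox genes of these groups mark posterior levels of the body axis.

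**Figure D3:**
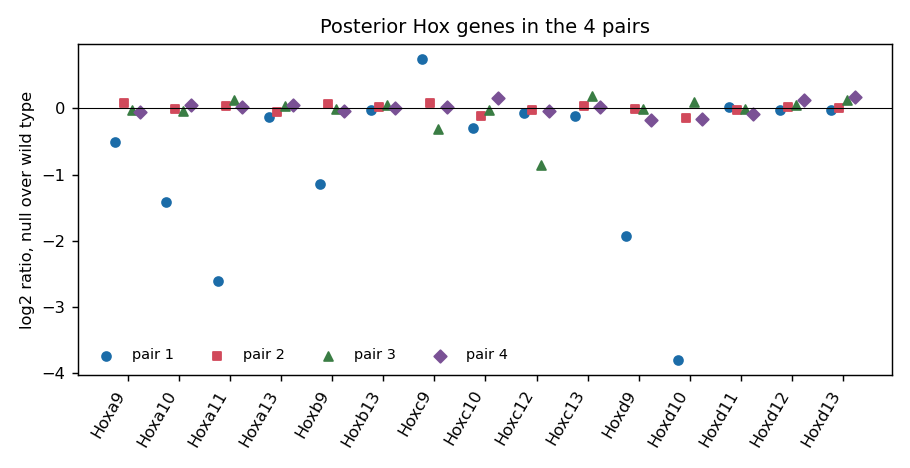
Log2 ratio of null over wild type of 15 posterior Hox genes (mean of their probes), with 1 symbol per pair and genes along the horizontal axis. Pair 1 reaches -3.81 for Hoxd10 and 0.75 for Hoxc9, and pairs 2 and 4 lie near 0.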

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

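A pair was singled out here when its gap to the nearest of the other pairs took up most of the range of all 4. For independent items not chosen by their values, chance does this for about 1 in 20, or about 4.45 of the 89 items examined. Found were 9, 6 of them in pair 1, 2 in pair 3 and 1 in pair 4. Eif2s3y counts among them both as a gene and as its single probe. Probes of the test between pairs entered because of their large range, and many items overlap. The 9 can therefore not be read as an excess over that rate. The tests of explanations in this part were all chosen after the results were seen.

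In pair 1, Eif2s3y stood at -4.56, as a gene and as its single probe, and Kdm5d at -2.42, with the other pairs at -0.04 to 0.90 and -0.06 to 0.13. Hoxd10 stood at -3.81, Atf3 at 1.70 against at most 0.15 elsewhere, and Kdr at -0.35 against -0.16 to -0.14. In pair 3 the pancreas median was 1.40, against -0.02 to 0.17, and Klf1 was at 1.60, against 0.09 to 0.32. In pair 4 the mesothelial median was -0.19, against 0.02 to 0.03. A signal outside the tests came from probe mTG035793, of an identifier class of 37 probes without genes in the tables used. It stood at 2.06 ± 0.30 (SD, n = 4), from 1.84 to 2.49 over the pairs, while the next largest mean of its class was 0.20 in size. Its adjusted p among all probes was 0.250.

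The goblet list was lowest in pair 1, with a median of -1.05. More distal gut in the wild-type sample of that pair may account for it, since 6 of 15 posterior Hox genes lay below -0.5 there and at most 1 in any other pair. Hoxd10, whose value prompted the choice of that set, is among the 6, and Hoxc9 went the other way, at 0.75. Hoxa13, Hoxb13, Hoxc13 and Hoxd13 lay between -0.13 and -0.02 in pair 1 and so did not share the fall. The Y-linked gene Eif2s3y at -4.56 shows that the embryos of pair 1 also differ in Y-linked expression, and sex and goblet level cannot be told apart within a single pair. Loss of LGR5 itself remains open as well, although without pair 1 the mean of the list shrank from -0.40 to -0.15 (adjusted p = 0.0189, and over all pairs 0.586 with an estimated correlation), and pairs 2 and 3 had medians of -0.006 and 0.06.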

How the results depend on the processing

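Leaving out pairs 1 and 3 together, all probes of the file, and leaving out probes discordant between dyes were chosen after seeing the data. Probes past the threshold numbered 0 in the main setting and under all alternatives run except the random pair block with a dye term, which gave 12, 2 higher and 10 lower, where Lgr5 also passed at its mean of -1.59. That fit takes part of its spread from arrays within pairs. Leaving out 1 pair at a time gave 0 to 0 probes, and -1.82 to -1.48 for Lgr5. Of the 11 list calls, 0 held with an estimated correlation and 0 with fry. Leaving out 1 pair gave 9 to 12 lists. Paneth, goblet, proliferation, fibroblast and endothelial lists stayed past the threshold under 12 of 14 settings, all but those 2. Those 12 all use the preset correlation, where p rests on the number of genes, so the count does not check that choice. Without 1 pair the mean ran from -0.076 to 0.42 for the erythroid list and from -0.076 to 0.62 for the liver list, negative without pair 3 alone. Without pairs 1 and 3 the mean turned to 0.10 for smooth muscle, past the threshold (adjusted p = 0.000624), and to 0.006 for enteric neurons and glia and -0.087 for erythroid genes, not past it (0.451 and 0.328). The cause was not tested. Probes differing between pairs numbered 5019 without the dye term and 1564 to 8928 without 1 pair, where fewer arrays enter. For single lists 33 calls were lost and 11 gained over all alternatives. For named genes and probes other than Lgr5, 5 calls were gained. None of them passed in the main setting, so none could be lost. Turned signs on the unpassed side numbered 21 for lists and 7 for genes. The 3 alternatives on missing values, and the one for the test between pairs, were not run because 0 values were missing. Signal over background is not given, so its effect on weak probes is unknown.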

Other observations

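The tests of explanations in this part were chosen after the results were seen, except those over sign patterns, and the camera tests among them use the preset correlation. Small p-values of these camera tests therefore rest on the number of genes, not on the number of pairs. The 4 pairs allow 8 sign patterns, too few for a share under 0.05. For probes the real number past the threshold was 0 and the highest other 0, and a count of 0 is met by 8 of 8 patterns whatever the data hold, so it tests nothing. For the lists, 2 of 8 patterns gave as many, with 11 in the real pattern and 12 at the highest of the others. The others ran from 6 to 12, so the preset correlation calls many lists with turned signs too. The count of 11 does not set the genotype direction apart. List by list, the real pattern had the lowest p of the 8 for the Paneth, proliferation, fibroblast, endothelial, leukocyte and stem cell lists, but not for goblet, enteric neuron, erythroid, pancreas, liver or immediate early genes.

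The 12 probes of the random-block fit were those of Lgr5, Wt1, Mfap5, Eln and Rnf43 and 7 others, named after their values were seen. These were Cxcl12, a chemokine, with a mean of -0.37, Fbln2, a matrix protein, at -0.74, Itm2a at -0.74, Acad10 at -0.71, Cd34 at -0.38, and the unnamed probes mMC004801 at -0.75 and mMA032663 at 0.48. Fgf15, an ileal hormone of enterocytes, also chosen after its values were seen, stood at 2.52, -0.15, 2.52 and 2.25 in pairs 1 to 4. Genes with unadjusted p under 0.01 and the same sign in all pairs were 17 of 697 on the chromosome of Lgr5 without Lgr5, against 181 of 14422 elsewhere (Fisher's exact test across genes, p = 0.0149, adjusted p = 0.174 over 21 chromosomes). It had the lowest p of the 21, with chromosome 1 next at 0.0166, and genes are not independent replicates.

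The Paneth list was higher in null ileum, and strain DNA carried with the targeted allele is argued against as the whole cause, because the 11 Paneth genes on other chromosomes than Lgr5 were also shifted up (camera adjusted p = 0.00622). More distal gut in the wild-type sample of pair 1 was not needed for the call, since the list stayed past the threshold without that pair (camera adjusted p = 0.00302). Its mean shrank from 0.46 to 0.27, and a part of the shift stays open to that cause. A difference in gut level in pairs 3 and 4 was not tested. Defa20 and the ileal gene Fgf15 were both above 0 in pairs 1, 3 and 4 and below 0 in pair 2. Of 15 posterior Hox genes, 1 and 0 lay below -0.5 in pairs 3 and 4. Pancreas and liver RNA would not raise the list in pairs 1 and 2, where the pancreas and liver medians were below 0. The list was up in these pairs alone (camera adjusted p = 0.000577). With 2 pairs that p rests on the number of genes, so it does not decide on this cause. Of these pairs, pair 1 is the one open to more distal gut. In pair 2 the list's median was 0.18, with Lyz1 at 0.61 but Defa20 and Defa21 at -0.28 and -0.006. Both causes acting together were not tested. At an adjusted p of 0.178 with an estimated correlation the shift itself is open, and so is an effect of LGR5 loss. For Lyz1, a neighbour of Lgr5, a strain variant cannot be told apart from an effect of LGR5 loss: 0 of the other genes near Lgr5 passed, which a variant acting on Lyz1 alone would also give.

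Fibroblast and endothelial lists were lower in null ileum at the preset correlation. With an estimated correlation, of 0.009 and 0.137, the adjusted p was 0.146 and 0.242, and with fry it was 0.0981 and 0.105. The shift itself is therefore open. The fibroblast estimate is below the preset 0.01, so correlation does not account for its higher p in that setting. That p goes with the 3 residual degrees of freedom used there. A dye effect is argued against, because both were lower in either dye orientation alone, with a highest adjusted p of 0.000758. Dilution of the null samples by pancreas or liver RNA would not lower these lists in pairs 1 and 2, where the pancreas and liver medians were below 0. The fibroblast medians there were -0.26 and -0.16, and the endothelial ones -0.10 and -0.21. These values argue against such dilution in those pairs alone, and pair 1 also holds the Hox and Y-linked differences. The higher camera adjusted p of both lists was 8.53e-05, which with 2 pairs rests on the number of genes. For blood these pairs cannot decide. In pair 1 the erythroid median was 0.05, with Hbb-b2 at 0.41, and the leukocyte median 0.21, and only pair 2 had an erythroid median below 0, at -0.28. A smaller share of the whole gut wall would lower smooth muscle too. The smooth muscle median exceeded the fibroblast median by 0.18 ± 0.15 (SD, n = 4; 95% interval -0.05 to 0.42), which leaves that open over the 4 pairs, although without pairs 1 and 3 the smooth muscle list was past the threshold upward (adjusted p = 0.000624, against 0.820 over all pairs), a call at the preset correlation for genes with an estimated one of 0.683, which says little. An effect of LGR5 loss also stays open, with no separate test.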
